A study of Mus musculus with 4 samples.

How the data were processed

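The deposited data were Visium spatial transcriptomes of formalin-fixed, paraffin-embedded mouse hearts, 1 library per section, with 2 sections per group. Groups came from the labels' treatment field: anti-PD-1 and anti-CTLA-4 alone, or both with an antibody that neutralizes IL-17A. The labels also give a batch number of 1 or 2 shared by the groups, used as the replicate number.

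For each section the authors deposited raw UMI counts per gene and spot under tissue, with Space Ranger 2.1.0 named in the matrix header. The submitters' processing notes name the mouse genome mm10 and Seurat 5.1.0, without saying what Seurat was used for, and the probe set is not given in the sources used here. Barcodes, features (Ensembl IDs with symbols) and spot grid positions are the other deposited values used here. The authors also deposited a score per gene and section, Moran's I over the spots under tissue, with its adjusted p value (p_value, adjustment method not stated) and the UMI total per gene. Those deposited totals equalled the sums over the matrix for every gene listed (19238, 19239, 19223 and 19219 genes). The deposited image scale factors were not used, since no image was analysed here. All 4 matrices list 19465 genes, among which 11 symbols are repeated. Coordinates come from a RefSeq gene table of the assembly GRCm38.p6, which is mm10.

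The section was the unit of replication. Counts were summed per section over all spots, over immune-rich spots and over the other spots. Genes were filtered with filterByExpr by group, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation of the whole sections was 17.0%. Immune-rich and other spots were compared, and the interaction with treatment tested, with the section as a block. The 20 panel genes were left out of these 2 tests because they define the spots. An interaction gene was taken as moving the same way when its direction was the same within both batches. Standard errors were derived from the fold change and the F statistic. A total of 45 gene lists of cell types, pathways, anatomy and handling were fixed before the data were examined, and 43 with at least 5 members tested were compared with camera on log CPM (prior count 2, preset correlation 0.01). Mitochondrially encoded and ribosomal protein genes were the 2 lists with too few members. camera was repeated with an estimated correlation, and fry was run as well.

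Each spot was thinned to 5000 UMIs, and spots below that depth were left out of the scoring and of both spot classes. The score is the sum over the leukocyte panel. The threshold was the smallest whole count that at most 10% of spots reach with every section weighted equally, which came to 30. Shares carry 95% Wilson intervals, which cover counting error only. A count of 3 corresponds to 0.0410 and 0.0453 CPM in the ICI-alone sections and 0.0627 and 0.0909 CPM in the antibody sections. Rings were counted in steps on the hexagonal grid, with up to 6 neighbours per spot and 0.5 CPM added before logs. The level of a list in a ring was the summed CPM of its members outside the panel, scaled by library size alone. Abundant members therefore weigh most. Regions came from log-normalized counts, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. Atrial-rich spots are those with over 1% of UMIs on 5 atrial genes.

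Genes are named by a fixed rule. It takes a panel of 27 genes whatever their values, and per test the 10 largest rises and 10 largest falls past the threshold with at least 10 CPM in 1 group and the same direction in both batches (in all 4 sections for spot classes). It adds up to 4 members with the smallest p per list. Predicted genes without a symbol name are skipped. A total of 2 genes that this rule picks are not reported here, though counts of named genes include them. Members of lists named within the spot classes (Gzma, Tbx21, Lag3, Lck, Foxp3, Spp1, Mrc1, Cxcl1) were chosen after their values were seen.

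The batch numbers could pair sections across groups. The correlation across 18817 genes of the deviations of same-batch sections was 0.176, a value over genes and not over independent samples, and the blocked fit was kept as an alternative. The other alternatives were DESeq2 1.42.0, its size factors in edgeR, scaling by library size alone, no filter on low counts, a filter at 10 CPM in 2 sections or sums, leaving out each section, limma on mean log values per spot, sections thinned to an equal total of 33005923 UMIs, and leaving out atrial-rich spots, spots under 1000 UMIs or the 20 most abundant genes. For spots, thresholds of 5% and 20%, thinning to 2000 UMIs, no thinning, and ranking by the T cell or macrophage list were tried. A lone section left in a group was assumed to vary like the other group.

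The steps were tested on simulated data, in which 100 genes were changed at each fold size. The changed genes were drawn from those with a mean of at least 10 CPM, and all genes were given the same dispersion. Recovery of lower or more variable genes was not measured. At a log2 change of 1, 71% of changed genes were recovered among 18681 in whole sections, 64% among 17949 in other spots, 56% among 12589 in immune-rich spots, 94% among 15108 between spot classes and 21% among 17334 for the interaction. At a log2 change of 2 the recovery was 100% for the first 4 of these tests and 93% for the interaction. False calls numbered 10, 5, 10, 3 and 6. Of the 43 lists, the 1 changed list passed with a camera adjusted p of 3.15e-42 and 1 other list passed too. Genes were simulated independently of each other. In the data the estimated correlation within a list was 0.73 for matrix genes and 0.965 for oxidative phosphorylation. False list calls among correlated genes were therefore not measured. Grid steps equalled an independent search at 900 of 900 positions, and Moran's I was 0.954 for a simulated gradient and 0.0025 for shuffled values. No caller of mixed spots was run, since a spot covers several cells by design.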

Results

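Visium spatial transcriptomes were analysed for 4 formalin-fixed, paraffin-embedded heart sections, 1 per library. The wild type FVB/NJ mice had been immunized with a peptide of MyHCα, the cardiac myosin heavy chain alpha, and given 2 immune checkpoint inhibitors (ICIs), antibodies against PD-1 and CTLA-4. In 2 sections the mice had received the ICIs alone, the group in which the labels record myocarditis, and in the other 2 they had also received an antibody that neutralizes IL-17A. The ICI-alone replicates held 2503 and 3052 spots under tissue with 73167202 and 66255242 UMIs (unique molecular identifiers). The antibody replicates held 2604 and 2585 spots with 47882576 and 33005923 UMIs. Median UMIs per spot were 27912 and 20623 with ICIs alone and 18342 and 12298 with the antibody, and median genes per spot were 6272, 5764, 4955 and 4192 in the same order. Spots rich in atrial transcripts were found in antibody replicate 2 alone (164 spots, 6.34%). Scaled by library size alone, Nppa lay there at 5844 CPM with them and at 788 CPM without them. Levels are given as TMM-normalized CPM (UMI counts scaled by library size), mean ± SD with n = 2 sections per group, and a positive log2 fold change means higher with the antibody. Nothing in the labels says that the sections came from separate animals, so p-values measure the spread between these sections. No untreated section was analysed here.

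The first comparison asked how transcripts of the whole heart section differed when IL-17A was neutralized during dual ICI treatment. Neutrophil alarmins, matrix genes and targets of IL-17 signalling were far lower with the antibody. S100a9 and S100a8, which together form calprotectin, fell from 259.7 ± 65.0 to 20.9 ± 3.71 CPM and from 102 ± 31.9 to 9.20 ± 1.04 CPM. Collagens and remodelling enzymes fell as well: Col1a1, the main chain of type I collagen, from 5150.2 ± 3383 to 408 ± 7.34 CPM, and Mmp3, a matrix metalloproteinase, from 94.2 ± 41.5 to 6.76 ± 2.50 CPM. Ky, a muscle peptidase gene, rose from 3.43 ± 1.38 to 19.4 ± 9.61 CPM, and Ccl17, a ligand of the chemokine receptor CCR4, from 15.7 ± 3.26 to 73.2 ± 37.9 CPM. By the edgeR quasi-likelihood test, 571 genes rose and 1658 fell among 18817 tested. With the shared batch number as a replicate block, 3839 genes passed (1520 rose, 2319 fell), of which 2226 were shared in the same direction. With scaling by library size alone the split was 840 risen and 1029 fallen genes. A filter at 10 CPM left 821 genes past the threshold, and limma on mean log values per spot left 0 (3785 at an unadjusted p under 0.05). The count was 329 without antibody replicate 1, 515 without antibody replicate 2 and 4479 without ICI-alone replicate 1.

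The largest falls were those of Dio3 (log2 fold change -5.32 ± 0.48, adjusted p = 0.0175), which inactivates thyroid hormone, and Cthrc1 (log2 fold change -4.94 ± 0.49, adjusted p = 0.0175), a secreted product of activated fibroblasts. Dio3 dropped from 53.9 ± 33.6 to 1.35 ± 0.0197 CPM, and Cthrc1 from 87.9 ± 57.0 to 2.85 ± 0.491 CPM. Further large falls were seen for Col12a1 (-3.90, adjusted p = 0.0175), Mmp3 (-3.81, adjusted p = 0.0175), Col1a1 (-3.66, adjusted p = 0.0220), S100a9 (-3.64, adjusted p = 0.0155), S100a8 (-3.47, adjusted p = 0.0155) and Lcn2, an iron-sequestering acute phase protein (-3.36, adjusted p = 0.0225). Prg4, which encodes lubricin, and Ereg, a ligand of the EGF receptor, had log2 fold changes of -3.34 and -3.31. Among the largest rises, Ky had a log2 fold change of 2.50 ± 0.40, Mrgprh, a G protein-coupled receptor gene, 2.33, Mylk4, a muscle myosin light chain kinase, 2.33, Ccl17 2.22 ± 0.35, and Kcnj3, which encodes an inward rectifier potassium channel, 2.06. Aqp7, an aquaglyceroporin, had 2.04. Ptgfr, Smco1, Lrtm1 and Gal3st3 completed the 10 largest rises with log2 fold changes of 2.02, 1.92, 1.89 and 1.85. S100a9 (ENSMUSG00000056071) lies on chromosome 3, 90692630 to 90695721 in mm10 and S100a8 (ENSMUSG00000056054) on chromosome 3, 90669071 to 90670034. Col1a1 (ENSMUSG00000001506) lies on chromosome 11, 94936224 to 94953042, and Dio3 (ENSMUSG00000075707) on chromosome 12, 110279230 to 110281097. All 4 are protein coding. Col1a1 did not pass without antibody replicate 1 or 2, and its adjusted p ranged from 2.89e-19 to 0.271 over 15 alternatives. Mrgprh, Mylk4, Aqp7, Smco1, Lrtm1 and Gal3st3 failed without antibody replicate 1. Over all alternatives their highest adjusted p were 0.243, 0.214, 0.275, 0.263, 0.204 and 0.210. Lrtm1 and Ptgfr failed without antibody replicate 2, and the highest adjusted p of Ptgfr was 0.303.

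**Figure D1:**
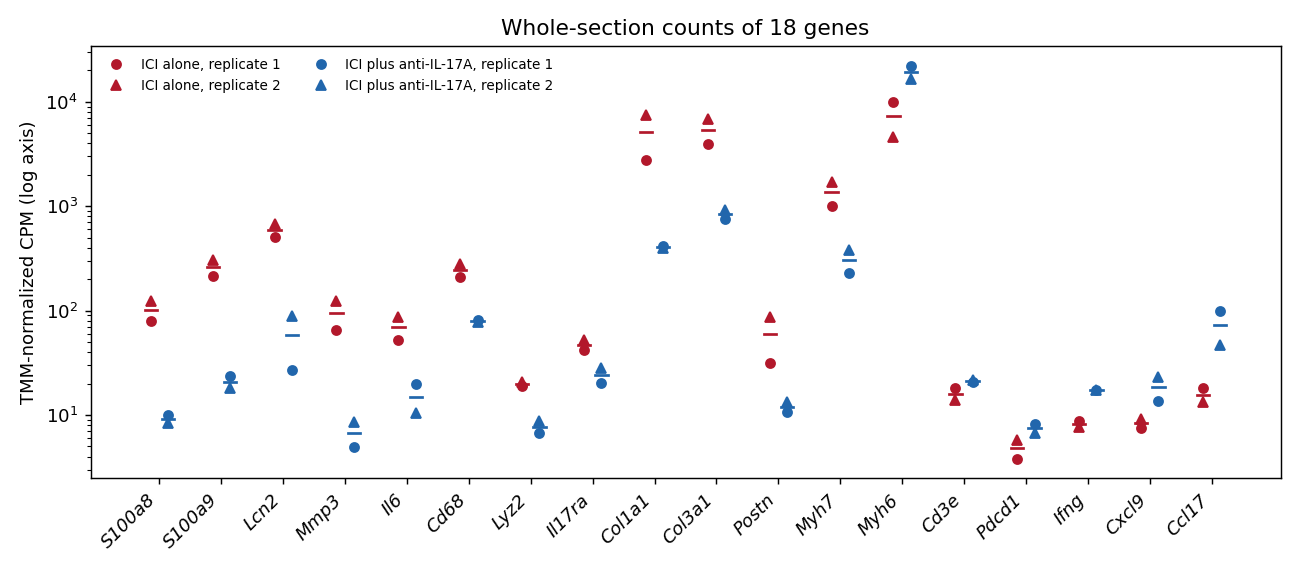
TMM-normalized CPM on a log axis of 18 genes in whole sections; points are single sections of each group and bars are group means (n = 2). S100a9 lies at 259.7 CPM on average with ICIs alone and at 20.9 CPM with the antibody, and Ifng at 8.25 and 17.4 CPM.

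Among the genes fixed in advance, the receptor of IL-17A and several myeloid and matrix genes fell. Il17ra, the receptor subunit that binds IL-17A, fell from 47.3 ± 7.45 to 24.1 ± 5.49 CPM (log2 fold change -0.97 ± 0.20, adjusted p = 0.0308), and Il6, an inflammatory cytokine, from 69.8 ± 24.8 to 15 ± 6.54 CPM (log2 fold change -2.21 ± 0.35, adjusted p = 0.0225). Il17a itself had a log2 fold change of 0.60 (adjusted p = 0.265) at 1.22 ± 0.111 to 1.82 ± 0.883 CPM. The macrophage genes Cd68 (log2 fold change -1.62 ± 0.20, adjusted p = 0.0210) and Lyz2 (log2 fold change -1.36 ± 0.18, adjusted p = 0.0210) fell, Cd68 from 244 ± 50.3 to 79.2 ± 2.98 CPM. The collagen gene Col3a1 (-2.69, adjusted p = 0.0225), the matricellular gene Postn (-2.31, adjusted p = 0.0270) and Myh7, the fetal and stress myosin of the mouse ventricle (-2.15, adjusted p = 0.0247), fell too. Myh7 went from 1358 ± 507 to 306 ± 107 CPM. Ifng, which encodes interferon gamma, rose from 8.25 ± 0.710 to 17.4 ± 0.0203 CPM (1.07, adjusted p = 0.0219), as did Cxcl9, an interferon-induced chemokine, from 8.31 ± 1.14 to 18.4 ± 6.60 CPM (1.14, adjusted p = 0.0384). Il17ra (ENSMUSG00000002897) lies on chromosome 6, 120463181 to 120483731 in mm10, Ifng (ENSMUSG00000055170) on chromosome 10, 118441046 to 118445894 and Myh7 (ENSMUSG00000053093) on chromosome 14, 54970684 to 54994626. The T cell genes Cd3e (0.40, adjusted p = 0.137), Cd4 (-0.23, 0.367) and Cd8a (0.30, 0.505) did not pass. Neither did the checkpoint genes Pdcd1 (0.65, 0.119), Ctla4 (0.46, 0.191) and Cd274 (0.64, 0.0786), although Cd274 did with batch as a block, at an adjusted p between 0.0155 and 0.354 over its alternatives. Gzmb (-0.22, 0.468), Cxcl10 (0.15, 0.715) and Ccl2 (-0.32, 0.191) did not pass. Of the cardiomyocyte genes, Myh6 (1.41, 0.129), Tnnt2 (0.048, 0.950), Atp2a2 (0.74, 0.313), Nppa (-0.56, 0.687) and Nppb (-0.43, 0.381) did not pass. Il17ra, Postn, Ifng, Col3a1 and Myh7 lost their calls without antibody replicate 1, and Cxcl9, Col3a1 and Myh7 without antibody replicate 2. Nppa gained one without the atrial-rich spots (-2.90, adjusted p = 0.0219), Myh6 without ICI-alone replicate 1, and Pdcd1 and Ctla4 without ICI-alone replicate 2. Adjusted p over the alternatives ranged from 0.000174 to 0.253 for Il17ra, from 1.95e-05 to 0.165 for Ifng and from 0.00142 to 0.348 for Cxcl9. The ranges were from 3.59e-18 to 0.231 for Col3a1, from 7.94e-10 to 0.411 for Postn and from 1.18e-09 to 0.202 for Myh7, and from 0.000368 to 0.479 for Myh6, from 0.0168 to 0.456 for Pdcd1 and from 0.0458 to 0.627 for Ctla4.

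Gene lists fixed before the data were examined were tested next, to see which kinds of gene moved together. Of 43 lists tested with camera, 16 fell and 6 rose with a preset correlation, and none of these 22 passed with an estimated correlation. The list of extracellular matrix and fibrosis had the smallest p: of 27 members, 0 rose, 23 fell and 4 did not pass over all genes, and 27 fell when adjusted over the list alone. Its median log2 fold change was -1.90 (camera adjusted p = 6.09e-15, adjusted p = 0.702 with an estimated correlation). Tnc, which encodes tenascin C, fell from 375 ± 156 to 39.0 ± 9.13 CPM (-3.26, adjusted p = 0.0175), Loxl2, a collagen crosslinking enzyme, from 263 to 55.1 CPM (-2.25, adjusted p = 0.0188) and Col8a1 had a log2 fold change of -1.90. In the myofibroblast and TGF-beta list 10 of 16 members fell (median -1.01, camera adjusted p = 1.28e-05, adjusted p = 0.702 with an estimated correlation), and 13 fell and 1 rose when adjusted over the list alone. In the fibroblast list 6 of 13 members fell (median -0.78, camera adjusted p = 0.00130, adjusted p = 0.702 with an estimated correlation), and 8 fell and 1 rose when adjusted over the list alone. Examples were Lum, a small proteoglycan (-1.48, adjusted p = 0.0217), and Pdgfra, a PDGF receptor gene (-0.90, adjusted p = 0.0286). In the proliferation list 14 of 16 members fell, the number also found when adjusted over the list alone (median -1.30, camera adjusted p = 5.61e-08, adjusted p = 0.702 with an estimated correlation). Top2a, a DNA topoisomerase gene, had -1.33, adjusted p = 0.0210. Pdgfra and Lum lost their calls without antibody replicate 1, and Lum also without antibody replicate 2. Their highest adjusted p over the alternatives were 0.254 and 0.215.

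The IL-17 response list (chemokines, cytokines and antimicrobial genes induced by IL-17 signalling) had 14 of 23 members fallen and none risen, and 17 fallen when adjusted over the list alone. Its median was -1.29 (camera adjusted p = 1.02e-08, adjusted p = 0.702 with an estimated correlation). The neutrophil-attracting chemokines Cxcl5 and Cxcl1 fell from 312 ± 76.6 to 42.9 ± 9.83 CPM (-2.86, adjusted p = 0.0175) and from 137 ± 36.5 to 21.5 ± 5.27 CPM (-2.68, adjusted p = 0.0175). In the neutrophil list 8 of 15 members fell (median -2.27, camera adjusted p = 2.85e-06, adjusted p = 0.702 with an estimated correlation), 9 when adjusted over the list alone. They included Csf3r, the G-CSF receptor (-1.84, adjusted p = 0.0175), and Mmp8, neutrophil collagenase (-2.55, adjusted p = 0.0210). S100a8, S100a9, Lcn2 and Mmp9 belong to both the neutrophil and the IL-17 response list, so the counts of these lists are not independent. In the macrophage list 10 of 17 members fell (median -0.99, camera adjusted p = 5.27e-06, adjusted p = 0.702 with an estimated correlation), 13 when adjusted over the list alone. Spp1, which encodes osteopontin, went from 581 ± 244 to 87.0 ± 45.6 CPM, Trem2, a lipid-sensing receptor, from 63.4 ± 19.2 to 18.8 ± 2.06 CPM and Gpnmb from 13.0 ± 2.60 to 2.72 ± 1.52 CPM. The leukocyte panel, 20 genes of T cells and myeloid cells together, had 11 members fallen and none risen over all genes, and 11 fallen and 2 risen when adjusted over the list alone (median -0.78, camera adjusted p = 0.00130, adjusted p = 0.702 with an estimated correlation). It was the 1 list past the threshold with fry (adjusted p = 0.0282). The inflammatory cytokine list had 4 of 16 members fallen, 6 when adjusted over the list alone (median -0.42, camera adjusted p = 0.00167, adjusted p = 0.721 with an estimated correlation). The complement list had 3 of 14 fallen, 7 when adjusted over the list alone (median -0.70, camera adjusted p = 0.000149, adjusted p = 0.702 with an estimated correlation). The chemokine list went both ways, with Ccl17 risen and Ccl9 fallen (-1.61, adjusted p = 0.0217). It had 2 members risen and 6 fallen of 19 (4 and 12 when adjusted over the list alone), at a median of -0.65 (camera adjusted p = 0.00368, adjusted p = 0.702 with an estimated correlation). Ccl9 did not pass without antibody replicate 2, its adjusted p reaching 0.204 over the alternatives.

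Lists of cytotoxic lymphocytes and of cardiomyocyte function lay higher with the antibody by camera with the preset correlation, and none of them passed with an estimated one. In the cytotoxic list 4 of 14 members rose, Ifng, the granzyme gene Gzma (11.9 to 23.0 CPM), and Eomes and Tbx21, the transcription factors of effector lymphocytes (1.22, adjusted p = 0.0304 and 0.96, adjusted p = 0.0434), and 8 rose when adjusted over the list alone. The median was 0.72 (camera adjusted p = 0.00196, adjusted p = 0.721 with an estimated correlation). In the calcium handling and ion channel list 5 of 18 members rose, 8 when adjusted over the list alone (median 0.78, camera adjusted p = 0.00348, adjusted p = 0.829 with an estimated correlation). Kcnj2, the main ventricular inward rectifier channel, went from 35.6 ± 7.21 to 89.5 ± 15.5 CPM (1.33, adjusted p = 0.0217). In the list of fatty acid oxidation, Ucp3, a mitochondrial carrier, rose (1.71, adjusted p = 0.0237) and Angptl4, an inhibitor of lipoprotein lipase, fell (-2.03, adjusted p = 0.0236), while 22 of 24 members did not pass, with the same counts when adjusted over the list alone and with 12 risen and 1 fallen with batch as a block (median 0.74, camera adjusted p = 0.00119, adjusted p = 0.829 with an estimated correlation). The medians of oxidative phosphorylation (0.54, 26 members) and of the sarcomere (0.55, 17 members) were positive, but no member passed by itself, nor when adjusted over the list alone. Their camera adjusted p were 0.00167 and 0.0270 (adjusted p = 0.829 and 0.829 with an estimated correlation). The interferon gamma list had 1 member risen of 24, Cxcl9, which did not pass when adjusted over the list alone (median 0.39, camera adjusted p = 0.0272, adjusted p = 0.829 with an estimated correlation). The camera calls of the interferon gamma list (adjusted p = 0.114), sarcomere (0.451), calcium handling (0.0794), oxidative phosphorylation (0.268) and fatty acid oxidation (0.0794) were lost without ICI-alone replicate 2. Those of sarcomere (0.245) and oxidative phosphorylation (0.120) were lost without antibody replicate 1 and that of the interferon gamma list (0.533) without antibody replicate 2. Gzma, Eomes and Tbx21 lost their calls without either antibody section. Their highest adjusted p were 0.204, 0.220 and 0.208 over the alternatives. Angptl4 lost its call without antibody replicate 1 (highest 0.313).

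Of the other lists that fell, cardiac stress and fetal genes had 7 of 16 members fallen (9 fallen and 1 risen when adjusted over the list alone; median -1.15, camera adjusted p = 2.05e-05, adjusted p = 0.702 with an estimated correlation). Examples were Hmox1, heme oxygenase 1 (-1.66, adjusted p = 0.0225), and Mt2, a metallothionein (-1.76, adjusted p = 0.0226). Cell death had 5 of 16 fallen, also 5 when adjusted over the list alone (median -0.48, camera adjusted p = 0.000194, adjusted p = 0.721 with an estimated correlation), among them Ripk3, a kinase of necroptosis (-1.01, adjusted p = 0.0225). Oxidative stress and unfolded protein had 6 of 17 fallen, 7 when adjusted over the list alone (median -0.52, camera adjusted p = 0.00391, adjusted p = 0.702 with an estimated correlation). MHC class II presentation had 1 of 11 fallen, the protease gene Ctss (-1.23, adjusted p = 0.0347), also 1 when adjusted over the list alone (median -0.60, camera adjusted p = 0.00565, adjusted p = 0.702 with an estimated correlation). The immediate early and handling list, fixed as a sign of tissue handling, fell as well, with 4 of 18 members fallen and 6 when adjusted over the list alone (median -0.51, camera adjusted p = 0.000134, adjusted p = 0.702 with an estimated correlation). Fos, an immediate early transcription factor gene, went from 64.0 ± 12.6 to 20.5 ± 1.75 CPM (-1.64, adjusted p = 0.0187). Without either antibody section Mt2, Ripk3 and Ctss lost their calls, as did Hmox1 without antibody replicate 2. Their highest adjusted p over the alternatives were 0.212, 0.245, 0.222 and 0.188.

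**Figure D2:**
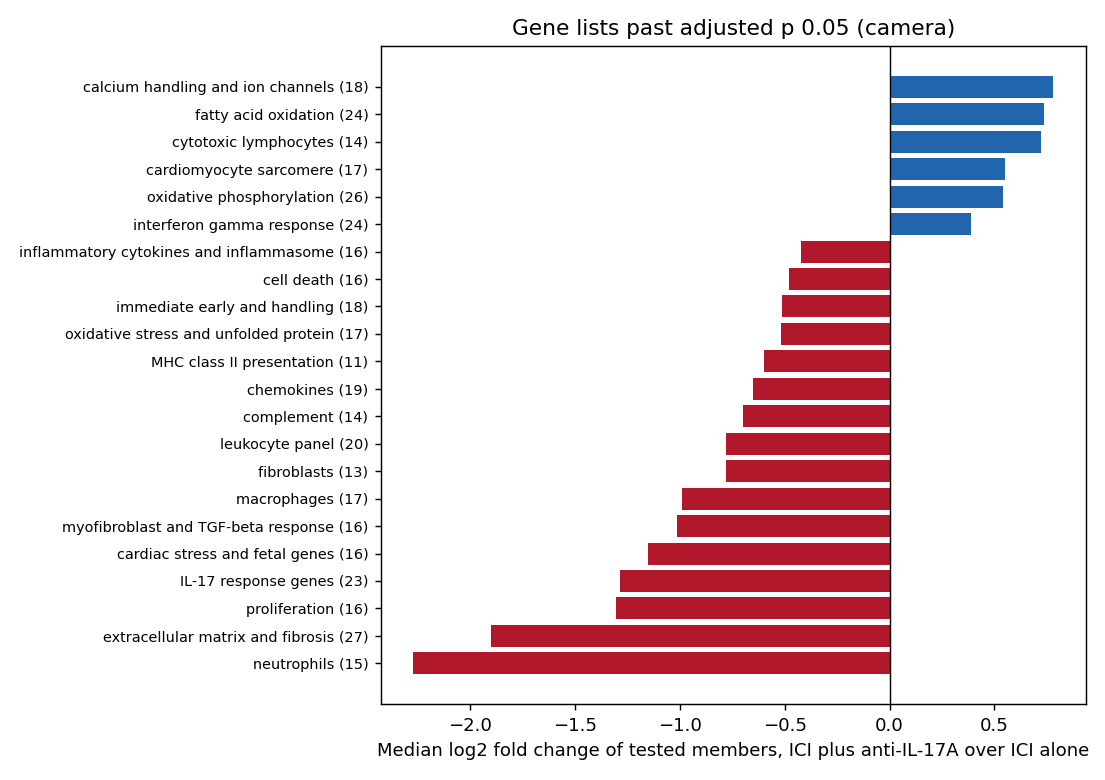
Median log2 fold change, antibody over ICIs alone, of the members of each of the 22 lists past an adjusted p of 0.05 with camera, with the number of members tested in brackets and bars drawn from 0. The bars run from -2.27 for neutrophils to 0.78 for calcium handling and ion channels; none of the 22 passed with an estimated correlation.

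A spot was called immune-rich when at least 30 of 5000 UMIs drawn from it fell on the leukocyte panel, a range of a score and not a tissue type. The question was how much of each section carried such transcripts. With ICIs alone 9.83% (245 of 2492 spots, 95% Wilson interval 8.72 to 11.1) and 17.6% (537 of 3048, 16.3 to 19.0) of spots were immune-rich, and with the antibody 8.24% (206 of 2499, 7.23 to 9.39) and 2.90% (74 of 2548, 2.32 to 3.63). The means were 13.7 ± 5.51% and 5.57 ± 3.78% (SD, n = 2), a difference of -8.15 percentage points (exact permutation p = 0.333, two-sided, the smallest that 2 against 2 sections can give). Ranked by the macrophage list instead, the shares were 9.51% and 20.7% with ICIs alone and 7.08% and 2.00% with the antibody. Ranked by the T cell list, the order turned: 4.17% and 3.25% of spots with ICIs alone and 9.20% and 8.52% with the antibody reached 4 UMIs, a difference of 5.15 points (exact permutation p = 0.333). That low threshold leaves 201, 213, 258 and 255 spots near it, more than the 104, 99, 230 and 217 that reach it. Without thinning, the panel's shares were 9.55%, 18.6%, 8.79% and 2.98%, with a difference of -8.21 points. With a threshold of 5% of spots the means were 8.01% with ICIs alone and 1.82% with the antibody (-6.20 points). With 20% they were 25.9% and 12.6% (-13.2 points). Spots with fewer than 5000 UMIs, 11, 4, 105 and 37 in the 4 sections, were left out, and 99, 183, 120 and 63 spots lay near the threshold.

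**Figure D3:**
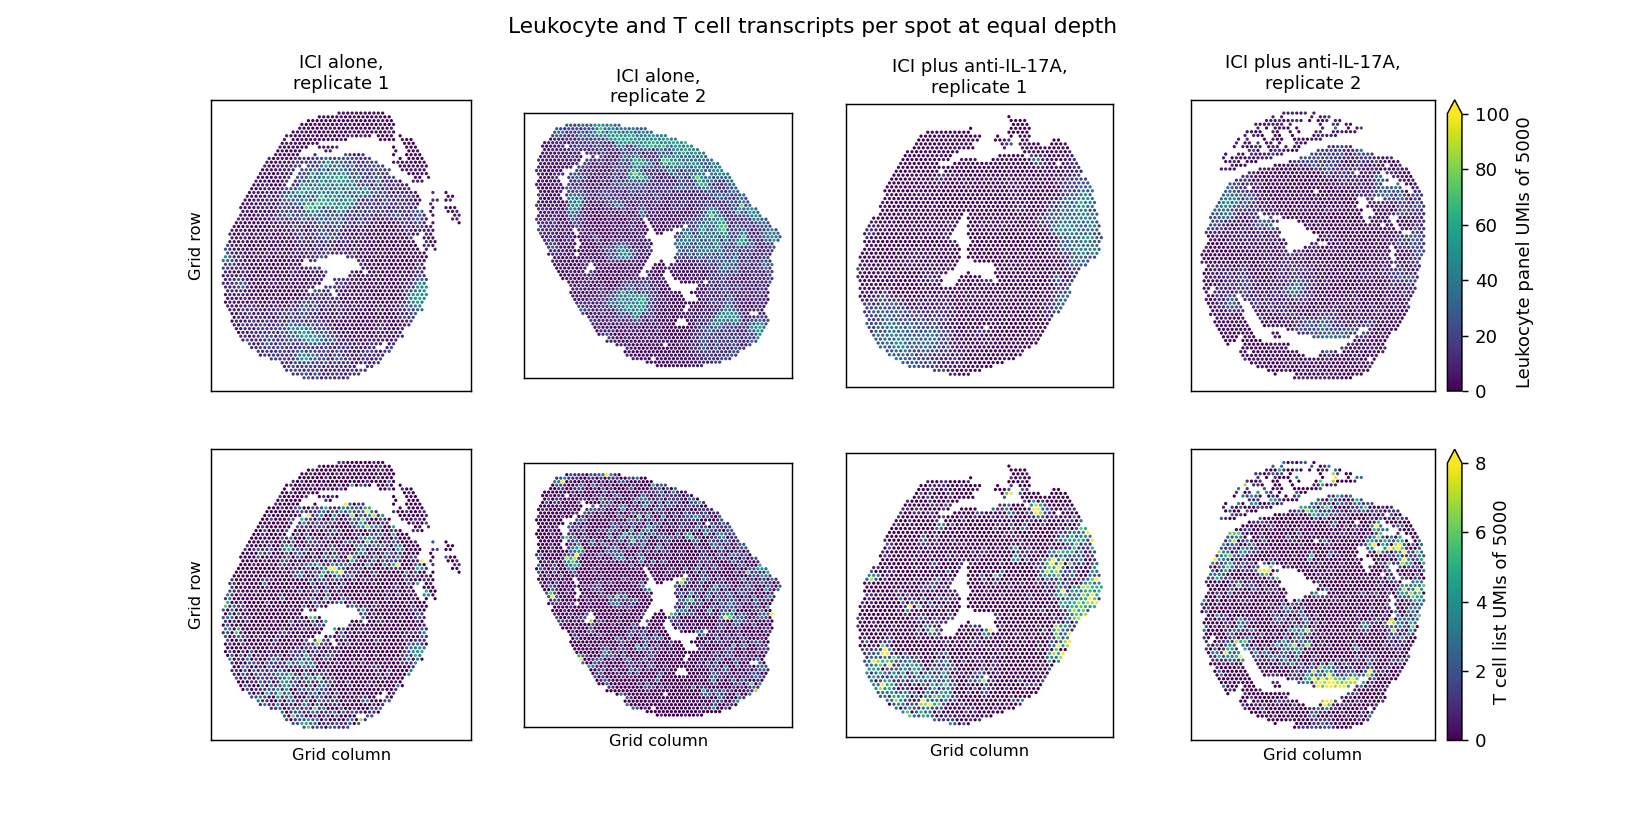
Spots of the 4 sections on the Visium grid (array column and row), coloured by UMIs of 5000 on the leukocyte panel (top) and on the T cell list (bottom). Spots with at least 30 panel UMIs make up 9.83% and 17.6% of the ICI-alone sections and 8.24% and 2.90% of the antibody sections.

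**Figure D4:**
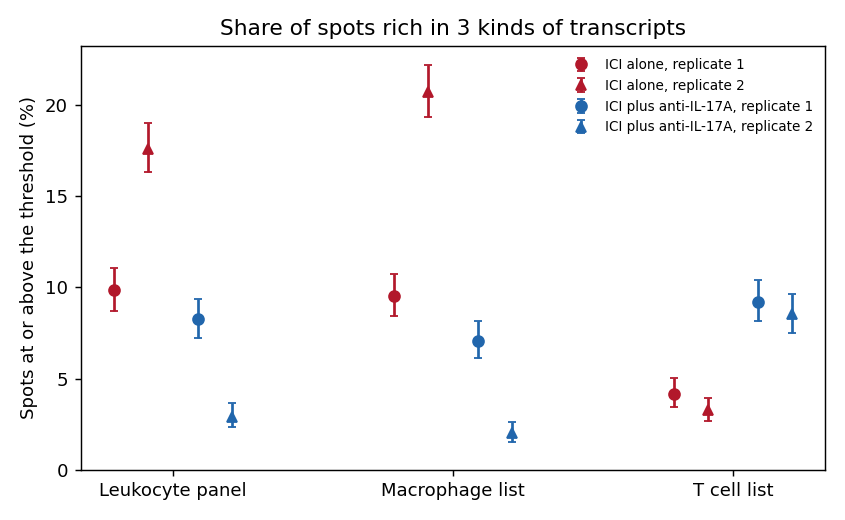
Percent of spots at or above the threshold per section when spots are ranked by the leukocyte panel, the macrophage list or the T cell list, with 95% Wilson intervals. The antibody sections lie below the ICI-alone sections for the panel and the macrophage list and above them (9.20% and 8.52% against 4.17% and 3.25%) for the T cell list.

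The comparison was then made within the immune-rich spots, to ask whether their composition differed between treatments. With the antibody these spots held more transcripts of T cell and cytotoxic genes and of several monocyte and dendritic cell genes. Transcripts of several macrophage and neutrophil genes were fewer. Cd3e, a chain of the T cell receptor complex, rose from 24.8 ± 4.97 to 71.6 ± 8.97 CPM, Ifng from 26.5 ± 7.52 to 111 ± 47.0 CPM and Il17a from 3.95 ± 0.668 to 14 ± 2.71 CPM. Cd68 fell from 665 ± 45.7 to 297 ± 69.3 CPM and S100a9 from 382 ± 99.0 to 119 ± 14.7 CPM. The chemokines Ccl17 and Ccl22, both ligands of CCR4, rose from 51.9 ± 30.2 to 496 ± 11.3 CPM and 34.9 ± 16.3 to 193 ± 1.92 CPM. Cd3e, Cd4, Cd8a, Cd68 and Lyz2 belong to the panel that defines these spots, so their levels depend in part on the choice of spots. In all, 460 genes rose and 451 fell of 13658 tested (edgeR), and 235 passed with batch as a block (113 rose, 122 fell; 221 shared). Without antibody replicate 1 edgeR called 0 genes (2927 at an unadjusted p under 0.05), while the log2 fold changes there were 1.63 for Cd3e, 2.43 for Ifng and 1.59 for Il17a. Without ICI-alone replicate 1, ICI-alone replicate 2 and antibody replicate 2 it called 363, 128 and 301. With all sections DESeq2 called 620, edgeR 329 with the 10 CPM filter and 123 with spots thinned to 5000 UMIs.

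Cilp, a cartilage and fibroblast matrix gene, had the largest rise (log2 fold change 4.13 ± 0.21, adjusted p = 0.00182), from 2.64 ± 0.150 to 46.6 ± 1.27 CPM. The next were AY761185 (3.62), Ccl17 (3.27, adjusted p = 0.0209), Col6a5 (3.13), Plet1 (2.74), the granzyme gene Gzmc (2.64, adjusted p = 0.0186), Apol7c (2.62), Eomes (2.57, adjusted p = 0.0321), Ccl22 (2.48, adjusted p = 0.0209) and the eosinophil chemokine Ccl11 (2.39, adjusted p = 0.0186). Of the fixed genes, Il17a had log2 fold change 1.88 ± 0.30, adjusted p = 0.0290, with log2 differences of 1.78 and 1.71 within batches 1 and 2. Cd3e (log2 fold change 1.52 ± 0.19, adjusted p = 0.0209), the checkpoint receptor gene Pdcd1 (log2 fold change 1.75 ± 0.24, adjusted p = 0.0234), and Ctla4 (1.09, adjusted p = 0.0435) rose. Ifng (log2 fold change 2.03 ± 0.31, adjusted p = 0.0271), Cxcl9 (2.02, adjusted p = 0.0245) and Cd4 (0.79, adjusted p = 0.0411) rose too. Cd68 (-1.16, adjusted p = 0.0291), Lyz2 (-1.25, adjusted p = 0.0291), S100a8 (-1.56, adjusted p = 0.0234), S100a9 (-1.67, adjusted p = 0.0209), Il6 (-1.03, adjusted p = 0.0321) and Col1a1 (-2.62, adjusted p = 0.0328) fell. The largest falls after those of Dio3 (-3.47) and Cthrc1 (-3.09) were those of Apoc2 (-3.02), the macrophage scavenger receptor gene Marco (-2.66, adjusted p = 0.0435), Col1a1, Prg4 (-2.58), Asb5 (-2.55), Col12a1 (-2.29), Tbx18 (-2.19) and Clec4a2 (-2.17). Il17ra (-0.17, adjusted p = 0.514), Cd8a (1.35, 0.0927), Cd274 (0.53, 0.0890), Gzmb (0.69, 0.151), Cxcl10 (0.58, 0.186), Ccl2 (0.058, 0.910), Col3a1 (-1.71, 0.0519) and Postn (-1.53, 0.0928) did not pass. The cardiomyocyte genes Myh6 (1.83, 0.0709), Myh7 (1.08, 0.0692), Nppa (-1.31, 0.101), Atp2a2 (0.56, 0.264) and Tnnt2 (-0.021, 0.985) did not pass either. With batch as a block Cd4, Ctla4, Col1a1, Prg4 and Apol7c lost their calls, at highest adjusted p over the alternatives of 0.414, 0.259, 0.178, 0.174 and 0.168. Without antibody replicate 1 none of the genes named here passed, with adjusted p of up to 0.190 for Il17a, 0.161 for Cd3e and 0.159 for Ifng over their alternatives, and Il17a also failed without ICI-alone replicate 2. Il17a (ENSMUSG00000025929) lies on chromosome 1, 20730905 to 20734496 in mm10.

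By list, 11 of 18 T cell genes rose in immune-rich spots and none fell (18 rose when adjusted over the list alone), at a median log2 fold change of 1.26. The T cell, cytotoxic and macrophage lists counted here include genes of the panel that selects the spots, and 11 of the T cell genes lie outside it. For 25 T cell and cytotoxic genes outside the panel the mean log2 rise was 1.33. Of 13 cytotoxic genes 8 rose (11 when adjusted over the list alone; median 1.47), and of 11 regulatory and exhausted T cell genes 8 rose (9 when adjusted over the list alone; median 1.23). Lag3, an inhibitory receptor gene (2.08, adjusted p = 0.0400), Gzma (2.06, adjusted p = 0.0234), Tbx21 (1.88, adjusted p = 0.0245) and the kinase gene Lck (1.59) were among those that rose, while Foxp3, the transcription factor of regulatory T cells, did not pass (0.49, adjusted p = 0.244). Of 16 macrophage genes 6 fell and 1 rose (9 and 1 when adjusted over the list alone; median -0.91), including Spp1 (-1.99, adjusted p = 0.0209) and the mannose receptor gene Mrc1 (-1.46, adjusted p = 0.0264). Of 12 neutrophil genes 5 fell (7 when adjusted over the list alone; median -0.91), and of 23 IL-17 response genes 10 fell and 3 rose (12 and 4 when adjusted over the list alone; median -0.71). Cxcl1 had -2.16, adjusted p = 0.00612. The rise was not particular to lymphocytes. Of 14 monocyte and dendritic cell genes 6 rose and 1 fell, at a median of 1.03 (7 and 2 when adjusted over the list alone). Of 12 B and plasma cell genes 1 rose, also 1 when adjusted over the list alone, at a median of 1.22. Of 14 genes of the IL-17 family and type 17 lymphocytes 1 rose, Il17a, and 1 fell (7 and 1 when adjusted over the list alone; median 0.83). Of 27 matrix genes 10 fell (16 fell and 1 rose when adjusted over the list alone; median -1.23). Scaling by library size alone moved the median of all genes from 0.0019 to 0.18 and the split from 460 risen and 451 fallen to 877 and 195. Without the low-count filter the split leaned the other way, with 407 risen and 1245 fallen. No member of any list passed without antibody replicate 1, where edgeR called 0 genes (2927 at an unadjusted p under 0.05).

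Outside the immune-rich spots matrix, neutrophil and IL-17 response genes were again lower with the antibody. S100a9 fell from 237 ± 63.3 to 13.3 ± 0.986 CPM (log2 fold change -4.15 ± 0.24, adjusted p = 0.00136) and S100a8 from 88.5 ± 28.6 to 5.51 ± 1.23 CPM (log2 fold change -4.01 ± 0.27, adjusted p = 0.00236). Dio3 (-5.66, adjusted p = 0.00719), Cthrc1 (-5.36, adjusted p = 0.00719), Col12a1 (-4.26, adjusted p = 0.00719), Mmp3 (-4.18, adjusted p = 0.00988), the gelatinase gene Mmp9 (-3.97, adjusted p = 0.0145), Col1a1 (-3.82, adjusted p = 0.0145), the crosslinking enzyme gene Lox (-3.67, adjusted p = 0.0140) and the B cell chemokine gene Cxcl13 (-3.63, adjusted p = 0.0209) were the other large falls. The checkpoint ligand gene Cd274 rose from 159 ± 8.01 to 319.9 ± 70.4 CPM (1.01, adjusted p = 0.0293), Ifng from 4.90 ± 0.496 to 11.6 ± 0.304 CPM (1.24, adjusted p = 0.0160) and Ccl17 from 9.60 ± 0.159 to 43.8 ± 24.1 CPM (2.19, adjusted p = 0.0149). In total 474 genes rose and 1400 fell of 18168 tested, and 5798 passed with batch as a block (2568 rose, 3230 fell; 1874 shared), 714 with spots thinned to 5000 UMIs and 1 with a filter at 10 CPM (9424 genes tested, 3144 at an unadjusted p under 0.05). Of 27 matrix genes 24 fell (27 when adjusted over the list alone), of 15 neutrophil genes 9 (11 over the list alone), of 23 IL-17 response genes 14 (16 fallen and 1 risen) and of 17 macrophage genes 6 (11). The immediate early and handling list moved the same way, with 6 of 18 members fallen and 0 risen (7 fallen over the list alone, median -0.49). In contrast, 3 of 14 cytotoxic genes rose (9 over the list alone) and all 18 T cell genes did not pass, nor did any over the list alone. The atrial genes Myl7 (9.52, adjusted p = 0.0412) and Mybphl (7.17, adjusted p = 0.0484) rose through antibody replicate 2, with log2 differences of 1.56 in batch 1 and 10.0 in batch 2 for Myl7. Stard10 (2.12, adjusted p = 0.0414), also an atrial gene, rose too and passed in 4 of 12 alternatives (highest 0.192). In the whole of that section, scaled by library size alone, Stard10 lay at 149 CPM with all spots and at 37.5 CPM without the atrial-rich spots. The other large rises were those of Ky (2.44), Mylk4 (2.28), Mrgprh (2.27), Aqp7 (1.96), Gnb3 (1.95, past the threshold in 4 of 11 alternatives) and Kcnj3 (1.95). The count was 12 without antibody replicate 1 and 45 without antibody replicate 2. Of the genes named here, S100a9 and S100a8 alone passed in both cases. The highest adjusted p over the alternatives was 0.0490 for S100a9 and 0.0520 for S100a8. The split was 323 risen and 520 fallen genes with scaling by library size alone.

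Of the remaining fixed genes in these other spots, Cd68 (-1.40, adjusted p = 0.0145), Lyz2 (-1.14, adjusted p = 0.0209), Il6 (-2.39, adjusted p = 0.0145), Il17ra (-0.98, adjusted p = 0.0388), Col3a1 (-2.85, adjusted p = 0.0145), Postn (-2.47, adjusted p = 0.0198) and Myh7 (-2.42, adjusted p = 0.0167) fell and Cxcl9 (1.13, adjusted p = 0.0463) rose. Il17a (0.34, adjusted p = 0.497), Cd3e (0.30, 0.277), Pdcd1 (0.55, 0.174) and Myh6 (1.31, 0.121) did not pass. Nor did Cd4 (-0.32, 0.320), Cd8a (0.21, 0.662), Gzmb (-0.20, 0.50), Cxcl10 (0.24, 0.578), Ccl2 (-0.27, 0.337), Nppb (-0.54, 0.365) and Tnnt2 (-0.060, 0.935). With batch as a block Myh6, Atp2a2 (0.65), Nppa (-0.74) and Ctla4 (0.53) passed too, at adjusted p ranging over the alternatives from 3.65e-06 to 0.460, 0.00368 to 0.798, 0.00286 to 0.909 and 0.0418 to 0.497. Each of the fixed genes that fell or rose lost its call without antibody replicate 1 and without antibody replicate 2, with Cd68 reaching an adjusted p of 0.107 and Il17ra of 0.140 over the alternatives.

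Immune-rich spots were next compared with all other spots of the same sections, whatever the treatment, to describe what the score selects. Inflammatory cytokine and MHC class II genes were higher in them and sarcomere genes lower. Mmp12, macrophage elastase, rose from 149 ± 71.3 CPM in other spots to 3077 ± 1065 CPM in immune-rich spots (n = 4 sections; log2 fold change 4.46 ± 0.29, adjusted p = 2.61e-05), and Arg1, arginase 1, from 261 ± 146 to 5071 ± 1973 CPM (4.4, adjusted p = 2.70e-05). Il17a went from 0.880 ± 0.196 to 8.0 ± 5.13 CPM (2.90, adjusted p = 0.000229) and Ifng from 9.10 ± 4.34 to 61.9 ± 50.2 CPM (2.52, adjusted p = 4.58e-05), both higher in 4 of 4 sections. Myh6, the main myosin of the adult mouse heart, fell from 16346 ± 9209 to 847 ± 691 CPM (-4.50, adjusted p = 7.85e-05). With the section as a block, 4457 genes rose and 4276 fell of 16109 tested by edgeR, 8408 of them the same way in all 4 sections. The other large rises were those of the chemokine gene Ccl24 (3.91), the cystine transporter gene Slc7a11 (3.85), Adam8 (3.77), Atp6v0d2 (3.72), the cytokine gene Il1a (3.68), Mmp13 (3.67), Stra6l (3.61) and F7 (3.61). The other large falls were those of Ces1d (-5.25), Car14 (-5.06), Lrtm1 (-4.99), Myh7b (-4.87), Asb14 (-4.83), Kcnip2 (-4.78), Gpr22 (-4.60), Myot (-4.54) and Aqp7 (-4.51). Cd274 (1.45), Pdcd1 (1.56), Gzmb (1.90), Ctla4 (1.26) and Il17ra (1.23) were higher in immune-rich spots, and Col3a1 (-0.16, adjusted p = 0.668) and Postn (-0.36, adjusted p = 0.135) did not pass. Cxcl9 (1.35, adjusted p = 0.000710), Cxcl10 (0.99, adjusted p = 0.000370), Ccl2 (0.98, adjusted p = 0.00282), Il6 (1.67, adjusted p = 0.00131), S100a8 (1.77, adjusted p = 0.0115), S100a9 (1.59, adjusted p = 0.0205) and Col1a1 (0.89, adjusted p = 0.0372) were higher too. Tnnt2 (-3.10, adjusted p = 0.000197), Atp2a2 (-3.05, adjusted p = 9.52e-05), Myh7 (-2.32, adjusted p = 0.0226) and Nppa (-1.56, adjusted p = 0.0118) were lower, and Nppb (-0.41, adjusted p = 0.511) did not pass. Over the alternatives the adjusted p reached 0.353 for S100a8, 0.519 for S100a9, 0.749 for Col1a1, 0.382 for Nppa, 0.100 for Myh7, 0.0957 for Il6 and 0.0591 for Cxcl9.

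By list, 11 of 11 MHC class II genes, 15 of 16 inflammatory cytokine genes, 15 of 16 cell death genes and 9 of 13 cytotoxic genes rose in immune-rich spots. Of 23 IL-17 response genes 15 rose and 1 fell, and of 24 interferon gamma genes 17 rose and 4 fell. The immediate early and handling list moved with them, with 10 of 18 members risen and 2 fallen (median 0.60). All 17 sarcomere genes, all 18 calcium handling genes and all 26 oxidative phosphorylation genes fell. Matrix genes went both ways, 11 up and 5 down of 27, and 9 of 13 fibroblast genes fell. Of 13 macrophage genes outside the panel 6 rose and 5 fell (median -0.26), while 9 of 11 T cell genes outside the panel and 7 of 14 neutrophil genes rose. Adjusted over each list alone, the counts were the same except for 10 risen T cell genes, 6 fallen macrophage genes, 10 fallen fibroblast genes and 5 fallen interferon gamma genes.

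The interaction test asked whether the difference between immune-rich and other spots was itself different with the antibody, and 419 genes passed of 18409 tested, 253 with a higher and 166 with a lower ratio of immune-rich to other spots with the antibody. The split depended on the setting: 142 higher and 127 lower with DESeq2, 561 and 577 with a threshold of 5% of spots, and 9 and 1 with 20%. The neutrophil genes S100a9 and S100a8 differed less between both kinds of spot with ICIs alone than with the antibody. S100a9 lay at 269 CPM in other spots and 356 CPM in immune-rich spots with ICIs alone, and at 14.8 and 99.3 CPM with the antibody (interaction log2 fold change 2.34 ± 0.25, adjusted p = 0.000561). Myh7 lay at 1873 and 109.8 CPM with ICIs alone and at 345 and 213 CPM with the antibody (interaction log2 fold change 3.26 ± 0.36, adjusted p = 0.000611). Pdcd1 had a higher ratio with the antibody (1.07, adjusted p = 0.0464), while Il17a (1.34, adjusted p = 0.114), Ifng (0.62, adjusted p = 0.272), Cxcl9 (0.80, adjusted p = 0.0913) and Il6 (1.09, adjusted p = 0.0863) did not pass. Nor did Il17ra (0.72, 0.0913), Postn (0.83, 0.0859), Gzmb (0.79, 0.150), Col3a1 (1.04, 0.241), Col1a1 (0.97, 0.293), Cxcl10 (0.18, 0.782), Ccl2 (0.15, 0.866), Ctla4 (0.38, 0.429) and Cd274 (-0.61, 0.353). The cardiomyocyte genes Myh6 (0.42, 0.790), Tnnt2 (-0.15, 0.931), Atp2a2 (-0.22, 0.871), Nppa (0.0054, 0.998) and Nppb (1.16, 0.646) did not pass either, and panel genes such as Cd3e were not tested here. Of 16 proliferation genes 10 had a higher ratio, of 15 neutrophil genes 7, of 23 IL-17 response genes 7, of 27 matrix genes 7 and of 11 T cell genes outside the panel 3. Adjusted over each list alone the numbers were 14, 10, 13 (and 1 lower), 16 and 7. The ratio was lower for 3 of 18 calcium handling genes, 3 of 24 fatty acid oxidation genes and 2 of 13 smooth muscle and pericyte genes. Of 14 endothelial genes 3 had a lower and 1 a higher ratio. Over each of these lists alone it was lower for 3, 8, 4 and 6 and higher for 0, 1, 0 and 1. The count was 84 without ICI-alone replicate 1, 15 without ICI-alone replicate 2, 254 without antibody replicate 1 and 1990 without antibody replicate 2. Pdcd1 lost its call without ICI-alone replicate 1, ICI-alone replicate 2 or antibody replicate 1, its adjusted p ranging from 0.0232 to 0.558 over 10 alternatives, while the adjusted p reached 0.148 for S100a9 and 0.0726 for Myh7.

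Levels were also followed with distance from the immune-rich spots, to see how far their signature reaches into the tissue. In spots adjacent to immune-rich ones, 25 of 42 lists were higher than in spots more than 3 steps away in all 4 sections, 11 were lower in all 4 and 6 were mixed. The 25 include the anatomical lung list (1.14 ± 0.40), whose 7 genes summed to 3.93 CPM in adjacent and 2.11 CPM in farther spots of ICI-alone replicate 2, and mast cells and eosinophils (1.28 ± 0.17). These values compare the summed CPM of each list, so they need not hold for most of its members. The sum of inflammatory cytokine genes was higher by 3.44 ± 0.90 on the log2 scale (SD, n = 4) and that of cytotoxic genes by 2.40 ± 0.71. The sum of T cell genes outside the panel was higher by 2.13 ± 0.78 and that of matrix genes by 1.45 ± 0.34, each in 4 of 4 sections. Sarcomere genes (-1.71 ± 0.27), fatty acid oxidation genes (-1.73 ± 0.26) and fibroblast genes (-0.33 ± 0.13) were lower in 4 of 4. The exact sign-flip p was 0.125 for each, the smallest that 4 sections can give. The T cell gradient averaged 1.51 with ICIs alone and 2.74 with the antibody, a difference of 1.23 (exact permutation p = 0.333). It was not particular to T cells: the gradient was also steeper with the antibody by 1.88 for B and plasma cells, 1.64 for neutrophils, 1.16 for chemokines and 1.15 for IL-17 response genes.

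Spatial autocorrelation, which is high when neighbouring spots carry alike levels of a gene, was read from the authors' deposited table of Moran's I. In the authors' deposited table Postn had values of 0.391 and 0.521 with ICIs alone and 0.0654 and 0.0710 with the antibody, and Col1a1 0.794 and 0.788 against 0.529 and 0.445. Over the matrix list the medians in the authors' deposited table were 0.568 and 0.537 with ICIs alone and 0.290 and 0.206 with the antibody, and 23 of 27 members had both antibody sections below both ICI-alone sections. Values for Ifng in the authors' deposited table were 0.271 and 0.163 against 0.428 and 0.315, for Pdcd1 0.0588 and 0.0792 against 0.305 and 0.175, for Cxcl9 0.207 and 0.180 against 0.444 and 0.305 and for Il17a 0.0609 and 0.0397 against 0.144 and 0.0859. Moran's I depends on depth, and the ICI-alone sections were the deeper ones. It can also depend on a gene's own level, which thinning does not equalize. In whole sections Col1a1 and Postn were lower and Ifng and Cxcl9 higher with the antibody. A change in spatial arrangement was therefore not parted from a change in level. Computed again with every spot thinned to 5000 UMIs, the median over the matrix genes of the difference between groups was -0.135, against -0.251 without thinning. The difference became -0.190 from -0.436 for Postn, -0.353 from -0.299 for Col1a1, 0.116 from 0.150 for Ifng, 0.0944 from 0.185 for Pdcd1, 0.126 from 0.204 for Cxcl9 and 0.0415 from 0.0888 for Il17a. Of the 27 fixed genes 7 then lay farther from the difference of the authors' deposited values than the spread within groups.

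Joint clustering of all spots gave 15 regions, numbered by size, of which 7 held over 90% ICI-alone spots, 5 over 90% antibody spots and 3 a mixture. Some belong to 1 section more than to 1 treatment: 95.9% of region 11 came from ICI-alone replicate 1, 94.2% of region 13 from ICI-alone replicate 2 and all of region 14 from antibody replicate 2. Region 8, led by Gpnmb, Mmp12, Arg1 and F7, made up 7.39% and 14% of the ICI-alone sections and at most 0.0384% of either antibody section, and 93.0% of its spots were immune-rich. Region 12, led by Ccl24 and Ccl17, made up 0.160% and 0.0983% against 7.72% and 1.62%, with 74.4% of its spots immune-rich. Region 6, led by Ccl17, Cxcl9, Ccl11, Ccl22 and Ifng, took 0.200% and 0.0328% against 11% and 16.6%, with 13.6% immune-rich. Region 4, led by Tnc, Dio3 and Col12a1, took 6.99% and 29.7% of the ICI-alone sections and was 1 of the 7 regions of over 90% ICI-alone spots. Region 3, led by Myh7 and Cxcl13, took 7.71% and 31.3% against 0.0384% and 0.116%. Region 15, led by the smooth muscle genes Myh11 and Tagln, was shared, at 1.72%, 0.524%, 1.08% and 0.851%. The exact permutation p of these shares was 0.333 at the least, the smallest that 2 against 2 sections can give. The leading genes themselves differ between treatments. The sections were clustered together without correction for section or depth. Median UMIs per spot were 28400 in region 4 and 15798 in region 3, both mostly of ICI-alone spots, and 18104 in region 6, mostly of antibody spots. Differences between sections or in depth were therefore not parted from treatment.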

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

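The tests for nonspecific probe signal, a smaller macrophage share, fewer immune-rich spots, dilution by cardiomyocyte RNA and the splits of the spot classes were chosen only after the result was seen.

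The difference between immune-rich and other spots itself differed between the treatments for 419 genes, by the interaction test of edgeR (adjusted p between 0.000561 and 0.0464 for the genes named). The log2 ratio of immune-rich to other spots was higher with the antibody by 3.96 for the B cell chemokine gene Cxcl13, 3.33 for the matrix gene Cilp and 3.26 for the fetal myosin gene Myh7. It was higher by 2.60 for Mmp3, 2.53 for the thrombospondin gene Thbs4 and 2.41 for the neutrophil chemokine receptor gene Cxcr2. The alarmin genes S100a9 and S100a8 had 2.34 and 2.32, and the nuclear receptor gene Nr4a3 had 2.32. The ratio was lower with the antibody for Nrep (-3.04), the monooxygenase gene Fmo5 (-2.59), the retinol-binding protein gene Rbp7 (-2.52), the homeobox gene Irx1 (-2.40) and the metalloproteinase gene Mmp15 (-2.36). Lrrc3b (-2.27), Colgalt2 (-2.22), Pfkfb1 (-2.19), Asb5 (-2.13) and the potassium channel gene Kcnj2 (-2.06) completed the named genes with a lower ratio. Cxcl13 stood at 32.6 CPM in other spots and 3.48 CPM in immune-rich spots with ICIs alone, and at 2.63 and 4.52 CPM with the antibody. Cilp, Cxcr2, Nr4a3 and Nrep passed in all 10 alternatives of this test (highest adjusted p = 0.0457, 0.0457, 0.0457 and 0.0472), and no other named gene did. The count was 84 without ICI-alone replicate 1, 15 without ICI-alone replicate 2, 254 without antibody replicate 1 and 1990 without antibody replicate 2.

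Matrix, neutrophil and IL-17 response genes were lower with the antibody, with a median log2 fold change of -1.73 over 61 members. A smaller number of immune-rich spots as the whole cause is argued against by the median of -1.88 in the other spots (-1.47 and -2.30 within batches 1 and 2). Those spots can still hold panel transcripts below the threshold, and the leukocyte panel fell there too (median -0.66, 8 of 20 members fallen and 0 risen). Less infiltrated tissue outside the immune-rich spots is therefore not excluded. Against dilution by cardiomyocyte RNA, the endothelial and smooth muscle genes of those spots had a median of 0.12, a gap of 2.01. The comparison cannot exclude dilution, since endothelial genes were lower together with sarcomere genes beside immune-rich spots. The log2 differences of their summed CPM from farther spots were -0.82 and -1.71, lower in all 4 sections, while smooth muscle genes had 0.035. With all sections thinned to equal totals the median was -1.69. Random thinning leaves the expected CPM ratios unchanged, so this value cannot exclude a difference tied to the depth or quality of the libraries. The antibody treatment named by the design, a difference in the extent of disease and differences between the tissue planes remain open and untested. Dilution and library depth remain open as well, and 2 sections per group are too few to part these candidates.

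In the immune-rich spots lymphocyte genes were higher with the antibody. Scaled by library size alone, 25 genes summed to 679 and 540 CPM with ICIs alone and to 1362 and 1748 CPM with the antibody. The gap was 683 CPM, against a rise of 15.3 CPM for as many of 1264 sensory receptor and keratin-associated genes. Those background genes stood at 8.02 and 10.9 CPM with ICIs alone and at 25.3 and 24.2 CPM with the antibody. They thus rose in proportion too. An added nonspecific probe signal of that size is argued against, while the relative rises were not tested. A smaller share of macrophage RNA would raise other cell types alike. The lymphocyte lists rose by 1.33 and the endothelial and smooth muscle lists by 0.036, a difference of 1.29. This difference argues against an equal rise of all other genes. It cannot exclude a shift among leukocyte genes, because the spots were picked by a panel sum. Monocyte and dendritic cell genes (median 1.03, 6 of 14 risen and 1 fallen) were higher there too. B and plasma cell genes had a median of 1.22, with 1 of 12 risen. Both tests ran on levels per section, which stay apart in every section of the groups, while the gene calls themselves end without antibody replicate 1, where edgeR called 0 genes (2927 at an unadjusted p under 0.05). A denser T cell infiltrate in the remaining foci may be a candidate explanation, as a hypothesis found and examined on the same sections; the score that picks the spots and the treatment stay open beside it. Counts of stained T cells per area of these foci in further animals of both groups would decide it.

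Atrial genes were high in antibody replicate 2 alone, and the test written in advance asked whether atrial tissue in that section carries them. The atrial genes that do not define atrial-rich spots (Nppa, Stard10, Nr2f2, Tbx5 and Dkk3) had a median log2 excess over the other sections of 1.62 with all spots and of -0.14 without the 164 atrial-rich spots. Scaled by library size alone, Nppa went from 5844 to 788 CPM in that section, Stard10 from 149 to 37.5 CPM and Dkk3 from 30.5 to 3.65 CPM. These values are consistent with atrial myocardium on 1 of the 4 sections, where the tissue plane is a candidate source, and a part of the treatment in it was not tested.

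For the 8733 genes that differed between immune-rich and other spots, 1 of 8 splits that part the spot classes of every section gave as many, the real one, and the highest of the others gave 0 by edgeR. With 8 splits a share under 0.05 cannot be reached. The classes were also cut from the same counts by the panel score, so genes that go with that score differ alike in every section by construction. The splits therefore cannot decide the question.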

How the results depend on the processing

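The tests chosen only after the data were seen are those without atrial-rich spots for the other and immune-rich spots, and those with spots thinned to 5000 UMIs for the other spots, the immune-rich spots and the interaction. Of 189 genes named for whole sections, 173 kept their side of the threshold with batch as a block and 16 gained a call, 187 kept it with DESeq2 size factors, 168 with library size alone and 189 without the low-count filter. Without antibody replicate 1, 64 lost their call, without antibody replicate 2, 51, and without ICI-alone replicates 1 and 2, 1 and 5. The blocked fit also gained 4 named genes in other spots and 1 list, valve and epicardium (adjusted p = 0.0444), and lost 5 named genes in immune-rich spots. It reversed no direction.

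For whole sections the count of 2229 became 3839 with batch as a block, 821 with the 10 CPM filter, which tests 9504 genes, and 0 with limma on mean log values per spot (3785 at an unadjusted p under 0.05; edgeR 2229, DESeq2 3315). Leaving out 1 section gave 329 to 4479. In other spots 1874 became 5798 with batch as a block, 843 with library size alone, 1 with the 10 CPM filter (9424 genes tested, 3144 at an unadjusted p under 0.05) and 714 after thinning, and leaving out 1 section gave 12 to 2778. In immune-rich spots 911 became 235 with batch as a block, 1652 without the filter, 329 with the 10 CPM filter and 123 after thinning, and leaving out 1 section gave 0 to 363 (2927 at an unadjusted p under 0.05 by edgeR without antibody replicate 1; DESeq2 620 with all sections). The interaction count of 419 became 269 with DESeq2, 63 with the 10 CPM filter, 1138 and 10 with thresholds of 5% and 20%, and 15 to 1990 on leaving out 1 section. Between spot classes the count of 8733 stayed within 6421 and 8799 in every alternative. Of the 22 lists past the threshold 0 passed with an estimated correlation and 1 with fry. The 10 CPM filter, with 32 lists tested, lost MHC class II, chemokines and oxidative stress. The number of regions was 10, 24 and 14 at lower and higher resolution and within sections, with an adjusted Rand index against the 15 regions of 0.698, 0.662 and 0.561, so spots change region and the shares depend on the setting. Of 27 Moran's I differences 7 moved after thinning (Cd8a, Lyz2, Cxcl10, Col3a1, Postn, Nppa and Nppb). The difference in immune-rich shares changed sign when spots were ranked by T cell genes (5.15 points). The filters also change the number of genes tested, and the cause of these changes, those under the filters included, was not tested.

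Some named genes reversed, none of them past the threshold. In other spots Tnnt2 had a log2 fold change of 0.015 with library size alone and 0.093 with the 10 CPM filter, and Gzmb had 0.015 after thinning. In immune-rich spots Il17ra had 0.015 with library size alone, Tnnt2 had 0.17 with library size alone, 0.072 with the 10 CPM filter and 0.12 after thinning, and Ccl2 had -0.082 without the filter. In the interaction Ifng had -0.013 after thinning and Nppa -0.077 with DESeq2 and -0.50 at 5%. For whole sections Cxcl10 had -0.0054 with limma. Between spot classes Col3a1 had 0.43 and Postn 0.25 at 20%, and the Schwann cell list had 0.15 in the adjacent ring at 20%. On leaving out 1 section, whole-section values ran from -0.25 to 0.46 for Cxcl10, -0.085 to 0.79 for Cd8a, -0.22 to 0.32 for Tnnt2, -0.031 to 1.00 for Il17a, -3.40 to 0.34 for Nppa and -0.53 to 0.019 for Gzmb. In other spots they ran from -0.21 to 0.56 for Cxcl10, -0.26 to 0.11 for Tnnt2, -0.17 to 0.67 for Cd8a and -3.56 to 0.14 for Nppa. In immune-rich spots they ran from -0.74 to 0.45 for Tnnt2, -0.38 to 0.28 for Ccl2 and -0.42 to 0.0083 for Il17ra, and between spot classes from -0.49 to 0.031 for Col3a1. In the interaction they ran from -0.91 to 0.61 for Tnnt2, -0.24 to 0.61 for Ccl2, -1.06 to 1.06 for Nppa, -6.30 to 2.12 for Nppb, -0.81 to 0.36 for Atp2a2 and -0.49 to 1.31 for Myh6. The cause was not tested. Antibody replicate 2 gave 74 immune-rich spots. Of simulated changes of 1 log2 unit in genes of at least 10 CPM, 56% were recovered in immune-rich spots and 21% for the interaction.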

Other observations

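Genes of dendritic cells, interferon and antibody-producing cells moved in lists that did not pass as a whole. Clec9a, a marker of cross-presenting dendritic cells, rose from 2.40 ± 0.753 to 5.52 ± 0.133 CPM (1.20, adjusted p = 0.0359; n = 2), while Itgam, an integrin of myeloid cells (-1.76, adjusted p = 0.0225), and Chil3, a chitinase-like product of alternatively activated macrophages (-2.52, adjusted p = 0.0329), fell. The monocyte and dendritic cell list had a median of 0.054, a mean of -0.19 and a test pointing down (camera adjusted p = 0.642). Of the type I interferon genes, Ifit3 rose from 17.3 ± 5.64 to 57.1 ± 19.5 CPM (1.72, adjusted p = 0.0235) and Oas1a fell (-0.79, adjusted p = 0.0258), with 2 of 17 risen and 1 fallen (median 0.34, camera adjusted p = 0.569). Mzb1, a gene of antibody-secreting cells, rose (1.17, adjusted p = 0.0293) and Cd22, an inhibitory receptor of B cells, fell (-1.11, adjusted p = 0.0427), in a list that did not pass (median 0.43, camera adjusted p = 0.534). The keratin genes Krt19 (2.00, adjusted p = 0.0225) and Krt8 (1.62, adjusted p = 0.0286), markers of the mesothelial surface, rose, and the valve and epicardium list had 5 risen and 2 fallen of 13 (median 1.21, camera adjusted p = 0.0920). In the vessel lists, Tie1, an endothelial receptor kinase, rose (0.79, adjusted p = 0.0264), as did the pericyte gene Rgs5 (0.97, adjusted p = 0.0273), and Acta2, smooth muscle actin, fell (-0.79, adjusted p = 0.0474). Clec9a, Oas1a, Mzb1, Cd22, Krt8, Tie1, Rgs5 and Acta2 lost their calls without either antibody section, and Chil3 did without antibody replicate 2. Their highest adjusted p over the alternatives were 0.183, 0.233, 0.203, 0.321, 0.215, 0.153, 0.176, 0.432 and 0.324. Cd22 and Acta2 lost them without ICI-alone replicate 2 too, and Krt19 without the atrial-rich spots, where its log2 fold change was 1.5 ± 0.41 against 2.00 ± 0.31 with them (adjusted p = 0.058; highest 0.182, with limma).

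The T cell list did not pass in whole sections (median 0.27, camera adjusted p = 0.0823, with no member of 18 past the threshold), nor did that of regulatory and exhausted T cells (median 0.22, camera adjusted p = 0.541). The list of the IL-17 family and type 17 lymphocytes had a median of 0.26, a mean of -0.10 and a test pointing down (camera adjusted p = 0.799), with 3 of 15 members fallen: Il6, Il17ra and Il1r1, the receptor of IL-1 (-1.23, adjusted p = 0.0240). Endothelial activation had 4 members fallen and 1 risen (median -0.38, camera adjusted p = 0.0646), with Selp, P-selectin, at -1.33, adjusted p = 0.0299. The other lists that did not pass were endothelial cells (median 0.35, camera adjusted p = 0.229), smooth muscle and pericytes (median -0.017, camera adjusted p = 0.642, with a mean of 0.0045 and a test pointing down), MHC class I presentation (median 0.024, camera adjusted p = 0.682, with a mean of -0.024 and a test pointing down), hypoxia (median -0.035, camera adjusted p = 0.541), glycolysis (median 0.14, camera adjusted p = 0.965) and mast cells and eosinophils (median 0.17, camera adjusted p = 0.642). Markers of tissue that a section could hold by its plane did not pass either: atrial myocardium (median 2.01, camera adjusted p = 0.0823), red blood cells (median 1.04, camera adjusted p = 0.149), skeletal muscle (median 0.42, camera adjusted p = 0.136) and lung (median 0.38, camera adjusted p = 0.117). The same held for thymus and lymph node (median 0.50, camera adjusted p = 0.323), adipose tissue (median 0.25, camera adjusted p = 0.541) and Schwann cells and nerve (median 0.15, camera adjusted p = 0.977). Of the thymus and lymph node list Cxcl13 fell (-3.23, adjusted p = 0.0312), a chemokine gene of B cell follicles. The T cell list passed without ICI-alone replicate 1 (adjusted p = 0.0274). Without antibody replicate 1 Selp, Il1r1, Il17ra and Cxcl13 failed, with highest adjusted p over the alternatives of 0.225, 0.268, 0.253 and 0.390.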
